A study of Rattus with 4 samples.

How the data were processed

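Gene-level values from 4 RIP-seq libraries of cultured rat cardiac cells were analysed, namely 2 inputs and 2 NONO IP libraries. Groups and replicate numbers came from the sample titles. Per the labels' protocols, RNA was treated with DNase, polyadenylated RNA was captured on beads, and libraries were made with a stranded mRNA kit. A table of counts and a table of RPKM values, each over 13731 genes and all 4 libraries, were used.

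The deposited counts are whole reads per gene, not normalised; every listed gene has at least 1 read summed over the libraries, and 2425 have exactly 1. The deposited RPKM values are reads per kilobase of gene scaled to a library total, per the file headers and checked on the values. Per the submitters' processing notes, HISAT2, HOMER and the rat genome build mRatBN7.2 were involved, with no role or version stated. The program that counted reads, its strand setting, its treatment of reads with several positions and the annotation release are not given in the sources used here. Reads of near-identical copies (U1, rRNA, snoRNA and ribosomal protein pseudogenes), of overlapping genes and of antisense genes are therefore uncertain. Gene symbols, types and chromosomes were taken from the deposited tables; 91.8% of the symbols matched the RefSeq gene table of the GRCr8 assembly, which was used only for names and for which genes lie inside others.

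Dividing counts by RPKM gave each gene's length up to a constant (relative gene length) and each library's RPKM total relative to Input replicate 1, from 461 genes with at least 30 counts in every library. The total behind the RPKM values was 2.38-fold larger in the NONO IP than in the inputs (mean over 2 libraries each), so that gene counts per RPKM total were 0.469-fold those of the inputs. The 2 units therefore scale the groups differently.

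The main test was edgeR's quasi-likelihood test (version 4.0.16, R 4.3.3) of NONO IP against input with TMM scaling after the filterByExpr filter. It kept 2920 genes, holding 91.1% of all counts, with at least 23 reads each. TMM factors were 0.844 and 0.861 for the inputs and 1.17 and 1.18 for the NONO IP. The common dispersion was 0.00458. P-values were adjusted by the Benjamini-Hochberg method and the threshold was 0.05; the counts of 2-fold changes use a fitted log2 fold change of at least 1 in size. SE is the log2 fold change divided by the root of the F statistic. Levels are TMM-scaled CPM as mean ± SD over 2 libraries. Where a group had no reads, the fold was bounded at 3 counts over the group, and where it had 1 to 3, an exact conditional 95% interval was used; reads carry no molecular identifiers, so intervals and floors cover counting error only.

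Replicates were compared by chi-square over genes with at least 20 counts in the pair. The statistic per degree of freedom was 1.12 for the inputs and 1.42 for the NONO IP, where 1 is sampling noise alone, and the libraries were kept as 2 per group.

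Gene lists were written before the data were examined, and 28 were fixed, covering gene groups around NONO, nuclear RNA, fibroblasts and other heart cell types. Of these, 17 had at least 5 tested members and were tested with camera on voom values (limma 3.58.1) with a preset correlation of 0.01, with the correlation estimated, and with fry. No list kept a camera call with an estimated correlation, where the lowest adjusted p was 0.182. That form of the test uses the 2 residual degrees of freedom of the 4 libraries. The glycolysis, C2H2 zinc finger and chromatin lists had estimated correlations of −0.061, −0.014 and −0.011, below the preset one, and lost their calls too. These adjusted p-values therefore cannot tell correlation within a list from a lack of libraries. By fry, which does not compare a list with other genes, 12 lists moved on balance one way, 2 up and 10 down. The other 11 lists had fewer than 5 tested members. With 3 libraries, voom weights failed, so camera used log2 CPM with a variance trend there. Gene types of the deposited table were added as sets after the data were seen.

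The genes named were chosen by a rule fixed before the data were examined. It takes Nono, Neat1 and Malat1 where present. It adds, for each direction, the 12 genes with the largest change among those past the threshold with a mean of at least 50 counts, a symbol that is not a placeholder, and both NONO IP libraries on one side of both inputs. From each tested list it takes up to 4 members with the smallest adjusted p on the side with more passing members. This gave 80 different genes; others are said to be chosen later. Some of the 80 are not reported here.

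The alternatives tried were DESeq2 size factors, library totals, the DESeq2 Wald test (version 1.42.0), limma-voom, no count filter, at least 50 counts in 2 libraries, limma on log2(RPKM + 1) and log2(RPKM + 0.1) for genes with an RPKM of at least 1 in 2 libraries, the replicate number as a block, a loess offset for gene length (span 0.5) without and with the block, and leaving out each library. Leaving out ribosomal RNA genes was added after the data were seen. RPKM fold changes are on the log2(value + pseudocount) scale, which understates the changes of low genes.

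The test was tried on simulated data. Counts were drawn for the real genes at means pooled over both groups, with the real library sizes and some genes changed. The common dispersion was used for every gene. The real groups differed at far more genes (871 higher and 786 lower), so the simulated setting is easier than the data. Of 2805 simulated genes tested for NONO IP against input, the test found 63.3% of those changed 2-fold, 91.8% of those changed 3-fold and 100% of those changed 4-fold or 8-fold, with 5.88% of calls false. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.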

Results

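RNA precipitated with an antibody to the protein NONO was compared with input RNA in cultured rat cardiac cells. NONO is an RNA- and DNA-binding nuclear protein of the DBHS family and a core protein of paraspeckles, nuclear bodies built on the long noncoding RNA Neat1. In RNA immunoprecipitation sequencing (RIP-seq), an antibody pulls a protein down with its RNA, and the recovered RNA is sequenced beside the input from which it was drawn. The 4 libraries fell into 2 groups, with 2 input libraries and 2 libraries precipitated with an anti-NONO antibody (NONO IP). Gene counts summed to 249548 and 238776 in the inputs and to 279410 and 264059 in the NONO IP libraries. This depth is shallow for a transcriptome of 13731 listed genes: 3 reads correspond to between 10.7 and 12.6 CPM (counts scaled to a common library total) per library. A read was counted on 9203 and 9124 genes in the inputs and on 10610 and 10627 in the NONO IP.

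The labels are not of one mind about these cells. The growth protocol describes a rat cardiac fibroblast line, whereas the titles name H9C2, a myoblast line from embryonic rat heart. The cell type label also assigns an empty vector to the inputs and NONO siRNA to the NONO IP libraries, so precipitation and knockdown are not separable by these labels. No library with a control antibody was among the 4. A difference given below is therefore one between the 2 sets of libraries, and the labels do not say whether replicates came from separate cultures, so that p-values measure the spread between these libraries only.

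Among the cell type markers listed, those of fibroblasts held the most input reads, 38217, nearly all of them on collagen genes. Col1a1, the alpha 1 chain of type I collagen, held 20647 of the input reads and Col1a2 held 10059, while the fibroblast markers Tcf21, Pdgfra and Thy1 held 5, 20 and 23. The 26 listed cardiomyocyte genes together held 463 input reads and 704 NONO IP reads, endothelial markers 232 and 254, and the 11 listed skeletal myoblast genes 37 and 39. Smooth muscle genes were also present, with 560 input reads of Acta2 and 205 of Myh11. Macrophage and leukocyte markers summed to 33 input reads and 7 NONO IP reads.

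The transcript of the targeted gene was itself low. Nono, on chromosome X, had 21 and 9 reads in the inputs and 3 and 3 in the NONO IP libraries. That is 7.51-fold less per scaled library in the NONO IP (exact conditional 95% interval of the ratio 3.07 to 22.1, for counting error only). Nono was below the count filter of the main test. In a fit over all 13731 genes the Nono log2 fold change was −2.64 (SE 0.58, edgeR adjusted p = 0.000772). The call ended with DESeq2 size factors (adjusted p = 0.132), without Input replicate 1 (0.0682), without NONO IP replicate 1 (0.425) and without NONO IP replicate 2 (0.393). Of the other DBHS genes, Sfpq had 41 and 38 input reads and 52 and 47 NONO IP reads (log2 fold change −0.26, SE 0.22, adjusted p = 0.328), and Pspc1 had 4 and 3 against 10 and 4. Neat1 and Malat1 were not found by symbol among the 13731 listed genes, so they could not be analysed here.

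Which RNAs NONO binds, the question the series title raises, was addressed by testing each gene between NONO IP and input; positions at exon and intron boundaries were not analysed here. Khdc4, which encodes a KH-domain splicing factor, Smad1, a signal transducer of the BMP pathway, and a large set of noncoding RNAs were higher in the NONO IP, while mitochondrial RNAs, ribosomal protein mRNAs and secretory pathway mRNAs were lower. Of 2920 genes tested, 871 were higher and 786 were lower at an adjusted p under 0.05, of which 745 were at least 2-fold higher and 570 at least 2-fold lower. The remaining 1263 did not pass. Log2 CPM values correlated across genes at a Pearson r of 0.937 between the inputs and 0.945 between the NONO IP libraries, against 0.584 between the group means.

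The balance of higher to lower calls depended on scaling and on the genes tested. Higher genes made up 52.6% of calls with TMM scaling and 73.3% with library totals, on the same 2920 genes. They made up 64.5% with no count filter (13731 genes), and 21.6% and 23.3% on the deposited RPKM scale with pseudocounts of 1 and 0.1, with another filter (7576 genes) and another test. Library totals moved the median log2 fold change of the tested genes from 0.02 to 0.48, and the RPKM scales moved it to −0.54 and −0.63. Changes of groups are given on the TMM scale, where the median gene lies near 0, and were judged under the other scalings relative to the median of all genes.

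Noncoding RNA classes stood apart from the mRNAs. Of the 57 lncRNA genes tested, 53 were higher and 4 lower in the NONO IP, with a median log2 fold change of 3.81 (3.23 with genes of no input reads set at a bound of 3 reads over the group). Small nucleolar RNAs, which guide modification of ribosomal RNA, were higher at 32 of 41 genes, with a median of 3.09, and lower at 3, LOC120102082 (SNORD17), LOC120095781 (SNORA81) and LOC120094011 (SNORA53). The 4 lower lncRNA genes were LOC120095881, LOC120095137, LOC120095551 and LOC120102809; these and the 3 snoRNA genes were named after their values were seen. Guide RNAs of the Cajal body, which guide modification of spliceosomal RNA, were higher at 8 of 9 genes (median 3.33, or 3.08 with bounds), and spliceosomal snRNA genes at 12 of 13 (median 2.11). All 13 snRNA genes were copies of U1, whose near-identical sequences share reads, so single copies are uncertain. The set is therefore not one of 13 separate RNAs, although its p-values below count it as such. These gene types were chosen as sets after the data were seen. Each was called by camera with the preset correlation, at adjusted p-values of 7.18e-13 for lncRNA, 2.52e-09 for snoRNA, 0.000336 for guide RNA and 0.000377 for snRNA genes. With an estimated correlation, on 2 residual degrees of freedom, the adjusted p-values were 0.0575, 0.258, 0.293 and 0.110. The estimated correlations were −0.009 for lncRNA, 0.366 for snoRNA, 0.777 for guide RNA and 0.003 for snRNA genes. The preset 0.01 is far below the snoRNA and guide RNA values, so their p-values with it are too small. The directions held under all scalings tried. Of the 57 lncRNA genes, 48 had fewer than 23 input reads, the lowest sum over libraries that was tested, as had 31 of the 41 snoRNA, 8 of the 9 guide RNA and 10 of the 13 snRNA genes. These passed the count filter through their NONO IP reads, so all 4 medians overstate the change of their class. The numbers of higher genes and the camera p-values rest on the same selection, so they are no separate support for a rise of the classes.

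In shares of all gene counts, lncRNAs made up 0.274% ± 0.00129 of the inputs and 1.47% ± 0.0247 of the NONO IP (SD, n = 2). SnoRNAs made up 0.276% ± 0.00413 and 1.11% ± 0.185, and guide RNAs 0.0247% ± 0.00531 and 0.411% ± 0.0994. Ribosomal RNA took 41.7% ± 0.786 of input counts and 32.0% ± 0.172 of NONO IP counts, although the labels describe poly(A) capture. The small Cajal body RNA 13 gene LOC120093414, on chromosome 6, rose from 9 and 5 reads to 841 and 559 (log2 fold change 6.03, SE 0.25, adjusted p = 1.7e-12). Among lncRNAs, LOC120097382 on chromosome 1 rose from 2 and 3 reads to 159 and 159 (5.35, SE 0.31, adjusted p = 1.45e-10). Pvt1, a lncRNA next to Myc, rose by 2.48 (SE 0.45, adjusted p = 0.000188). LOC120093414 and LOC120097382 were picked after their values were seen.

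**Figure D1:**
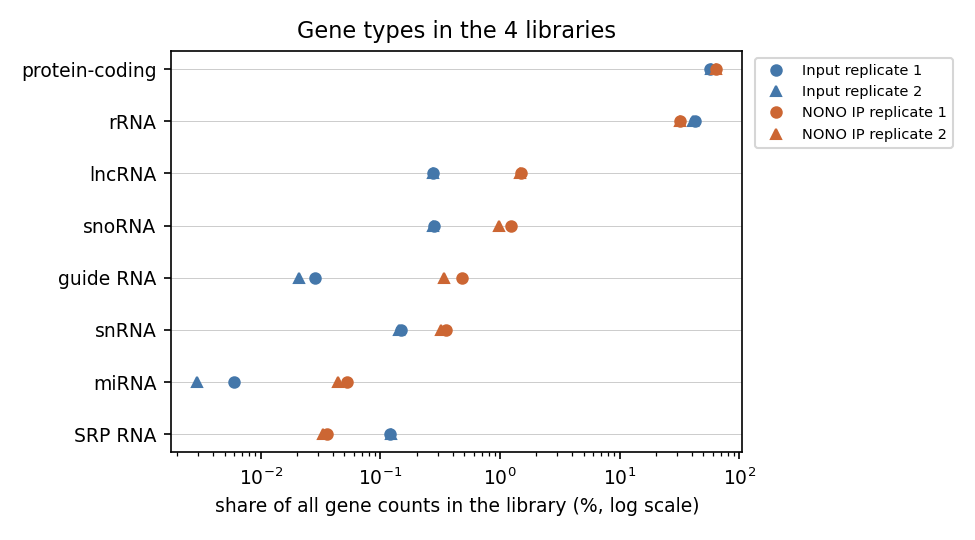
Share of all gene counts (x axis, percent, log scale) taken by 8 gene types (y axis) in each library, with inputs in blue and NONO IP in orange, circles for replicate 1 and triangles for replicate 2. Both NONO IP libraries lie above both inputs for lncRNA (1.49% and 1.45% against 0.275% and 0.273%), snoRNA, guide RNA, snRNA and miRNA, and below them for rRNA and for the signal recognition particle (SRP) RNA.

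Among protein-coding genes the split was even, with 757 of 2777 higher and 768 lower and a median log2 fold change of −0.03. The largest increase among those with a mean of at least 50 counts and a symbol that is not a placeholder was that of Khdc4, on chromosome 2, from 15.7 ± 0.298 to 1059 ± 73.0 CPM (log2 fold change 6.03, SE 0.25, adjusted p = 1.7e-12). Smad1, on chromosome 19, rose from 39.1 ± 2.95 to 765 ± 76.7 CPM (4.27, SE 0.23, adjusted p = 6.63e-11). Spaca6, a gene of sperm-egg fusion, rose by 4.23 (SE 0.17), the transcriptional repressor Erf by 3.62 (SE 0.22), Klhl29 by 3.33 (SE 0.14) and Rai1 by 3.32 (SE 0.18). Nufip2, the kinase gene Dyrk1a, Agfg1, Rbpms, Hnrnpf and the RhoGEF gene Kalrn rose by between 2.53 (Kalrn) and 3.18 (Nufip2). Both NONO IP libraries lay above both inputs for each of these 12 genes, as the rule for choosing them required.

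**Figure D2:**
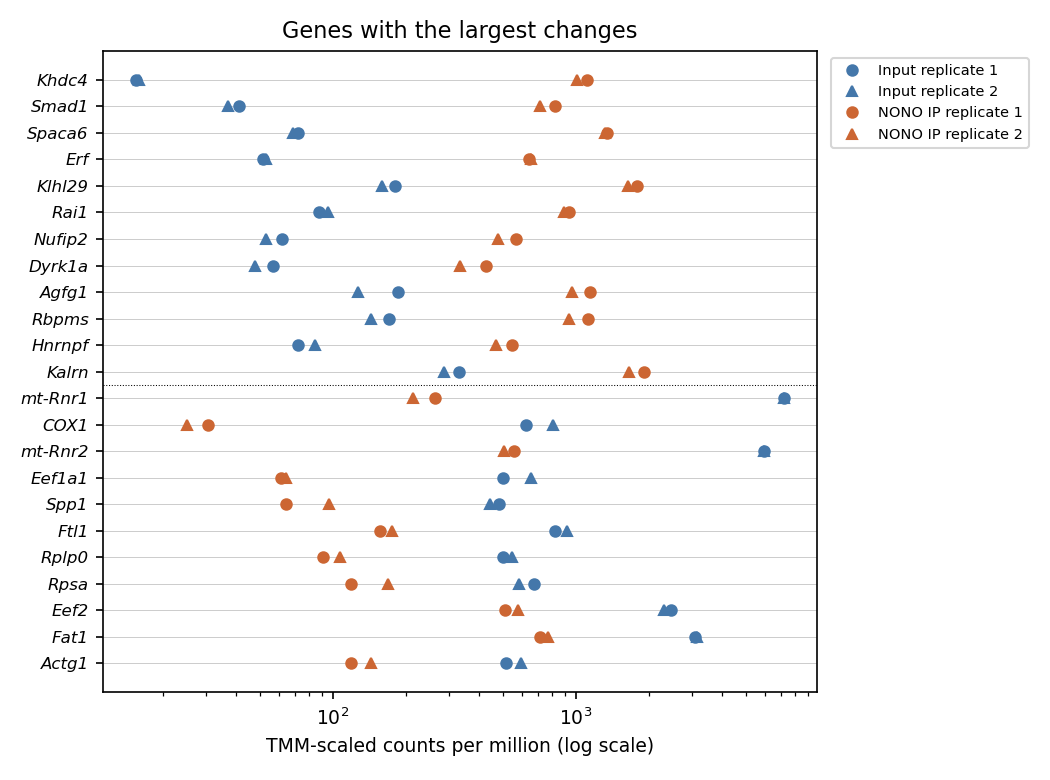
TMM-scaled CPM (x axis, log scale) in each library for the 12 genes with the largest increase (above the dotted line) and for 11 of the 12 with the largest decrease (below it); inputs are blue, NONO IP orange, circles replicate 1 and triangles replicate 2. Khdc4 lies at 15.5 and 15.9 in the inputs and at 1111 and 1007 in the NONO IP, and mt-Rnr1 at 7207 and 7218 against 264 and 214.

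Transcripts made inside mitochondria fell most among the lists. All 11 mitochondrially encoded genes tested fell, with a median of −3.57. The mitochondrial 12S rRNA mt-Rnr1 dropped from 7212 ± 7.86 to 239 ± 35.2 CPM (log2 fold change −4.91, SE 0.11, adjusted p = 9.68e-17). COX1, a subunit of cytochrome c oxidase, changed by −4.65 (SE 0.25), the 16S rRNA mt-Rnr2 by −3.48 (SE 0.09) and COX2 by −3.57 (SE 0.36). The camera adjusted p was 2.19e-07 with the preset correlation and 0.182 with an estimated correlation.

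All 40 cytoplasmic ribosomal protein genes tested fell, at a median of −2.26. Rplp0, of the ribosomal stalk, fell by 2.39 on the log2 scale (−2.39, SE 0.20, adjusted p = 1.92e-08), and Rpsa changed by −2.13 (SE 0.19). Rpl14 went from 58 and 57 reads to 0 and 1, a ratio of 173 with an exact counting interval of 30.4 to 6879. Ribosomal protein genes have many processed pseudogenes, which can share their reads. The 2 elongation factor genes among the largest decreases, Eef1a1 and Eef2, changed by −3.19 (SE 0.23) and −2.13 (SE 0.11). The other genes with the largest decreases were Spp1, osteopontin (−2.53), Ftl1, the ferritin light chain (−2.39), the cadherin gene Fat1 (−2.08) and Actg1, gamma actin (−2.08). The ribosomal protein list had an adjusted p of 6.3e-14 by camera (adjusted p = 0.182 with an estimated correlation). An offset for gene length brought its median to −1.12 and that of the mitochondrial list to −2.50.

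The secretory machinery fell as well. Of 24 genes of endoplasmic reticulum folding and secretion, 20 fell and none rose (median −1.39), among them the chaperone gene Hspa5 (−1.67, SE 0.18), P4hb (−1.36, SE 0.14), the translocon gene Sec61a1 (−1.69, SE 0.20) and the collagen chaperone gene Serpinh1 (−0.98, SE 0.12). Of 14 glycolysis genes, 11 fell and none rose (median −1.19), with Eno1 at −3.47 (SE 0.41), Gapdh at −2.75 (SE 0.33), Ldha at −2.34 (SE 0.27) and Pkm at −1.15 (SE 0.27). The camera adjusted p-values were 9.27e-07 and 0.00081. With an estimated correlation they were adjusted p = 0.184 and adjusted p = 0.182.

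Matrix genes, the main product of fibroblasts, fell too. Neither these nor the secretory and glycolysis genes were compared with genes of like input abundance, although abundant genes tended to be lower in the NONO IP. Of 43 collagen and fibrillar matrix genes, 38 fell at a median of −0.86, or 39 adjusted over the list alone. Fn1, fibronectin, dropped from 19554 ± 30.8 to 5548 ± 884 CPM (−1.82, SE 0.08, adjusted p = 6.05e-12), and Col12a1, Thbs1 and Fbn1 changed by −1.99 (SE 0.11), −1.33 (SE 0.07) and −1.38 (SE 0.09). The 1 member that rose was Bgn, the proteoglycan biglycan, at 0.25 (SE 0.09, adjusted p = 0.0213); it was named after its value was seen, and its change is smaller than the −0.54 by which an RPKM scale moved the median gene. The camera adjusted p was 8.55e-17 (adjusted p = 0.182 with an estimated correlation). Of 9 resident fibroblast markers, 6 fell (median −0.52), including Postn, periostin, at −3.16 (SE 0.28), Vim at −1.15 (SE 0.12), Col1a2 at −0.75 (SE 0.06) and Col3a1 at −0.49 (SE 0.06). Pdgfra rose, by 1.04 (SE 0.34). Postn, Col1a2 and Col3a1 are also members of the matrix list, so the fall of the fibroblast markers is not a separate result. Of 10 smooth muscle and pericyte markers, 8 fell (median −0.88), with Pdgfrb at −1.56 (SE 0.11), Acta2 at −1.40 (SE 0.12), Myh11 at −1.04 (SE 0.17) and Tagln at −0.76 (SE 0.14). Camera gave both lists adjusted p = 0.00081, and adjusted p = 0.182 with an estimated correlation. The call of the smooth muscle list ended with the length offset and replicate block together (adjusted p = 0.0566), where its median was −0.82. Tagln turned to 0.44 (adjusted p = 0.0199) with the length offset. Col3a1 and Tagln lost their calls with library totals, at −0.03 and −0.30, a scale on which the median gene lies at 0.48.

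Signalling genes of the TGF-β list did not move as one. Of 27 members, 13 fell and 4 rose (median −0.50, camera adjusted p = 0.00301, and adjusted p = 0.182 with an estimated correlation). Those that fell included Ltbp2, a binding protein of latent TGF-β, at −1.01 (SE 0.08), besides Pdgfrb and Acta2. Those that rose were Smad2 (4.33, SE 0.45), Smad3 (1.59, SE 0.44) and Smad7 (1.52, SE 0.12), transducers and an inhibitor of the pathway, and Pdgfra (1.04, SE 0.34); these 4 were named after their values were seen. Smad2 had 3 and 1 reads in the inputs and 73 and 54 in the NONO IP. The call of this list ended with the length offset (median −0.40, adjusted p = 0.242) and with at least 50 counts required in 2 libraries (median −0.67, adjusted p = 0.0570). That of the resident fibroblast markers ended with the length offset (adjusted p = 0.107) though the median went from −0.52 to −0.60, and on an RPKM scale with a pseudocount of 0.1 (adjusted p = 0.0534), where relative to all genes the median of the same 9 members stayed at −0.54.

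Lists of nuclear regulators were the ones to rise. Of 47 C2H2 zinc finger genes, a large family of DNA-binding transcription factors, 25 rose and 2 fell (26 and 2 adjusted over the list alone), with a median of 0.91; on the RPKM scales it was 0.25 and 0.36 over the 45 members tested on both, and −0.08 and −0.06 over all 120 members tested there, against medians of −0.54 and −0.63 over all genes. Zbtb7c (3.54, SE 0.49), Zfp710 (3.09, SE 0.39), Zfp827 (2.89, SE 0.31) and Zfp644 (2.74, SE 0.40) were among those that rose, and Zfp469 (−0.69) and Zfp106 (−1.50), named after their values were seen, fell. The camera adjusted p was 0.00131 (adjusted p = 0.182 with an estimated correlation). It was 0.0976 with no count filter, where the median over 265 members was 0.54 and that of all genes 0.24, so the rise was smaller there. With at least 50 counts in 2 libraries it was 0.367, at a median of 0.64 over only 5 members. Input reads were 2 and 2 for Zbtb7c, 5 and 5 for Zfp710, 9 and 5 for Zfp827 and 4 and 4 for Zfp644. These fall short of the 23 reads a tested gene had, so these 4 genes passed the count filter through their NONO IP reads. The number of higher members and the camera p-value of the 47 tested members rest in part on such selection. Of 42 chromatin regulator genes, 16 rose and 4 fell (median 0.36). The chromatin remodelling gene Arid1a rose by 2.28 (SE 0.20), the DNA methyltransferase gene Dnmt3a by 2.18 (SE 0.22) and Baz2a by 1.96 (SE 0.30); Smarcc1 (−3.08), Chd8 (−2.38), Ncor1 (−0.99) and Chd4 (−0.66), named after their values were seen, fell. The chromatin list had a camera adjusted p of 0.0319 (adjusted p = 0.184 with an estimated correlation). Its call ended with the length offset (adjusted p = 0.682), where the median turned to −0.05. It also ended on the RPKM scales (0.258 and 0.369, with 51 members tested), where the median of the 42 members was 0.29 and 0.34 relative to all genes, against 0.34 with TMM scaling. The call was lost without Input replicate 1 (adjusted p = 0.161, median 0.20), Input replicate 2 (0.0801, median 0.32) or NONO IP replicate 2 (0.0501, median 0.56), with 45 or 46 members tested.

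**Figure D3:**
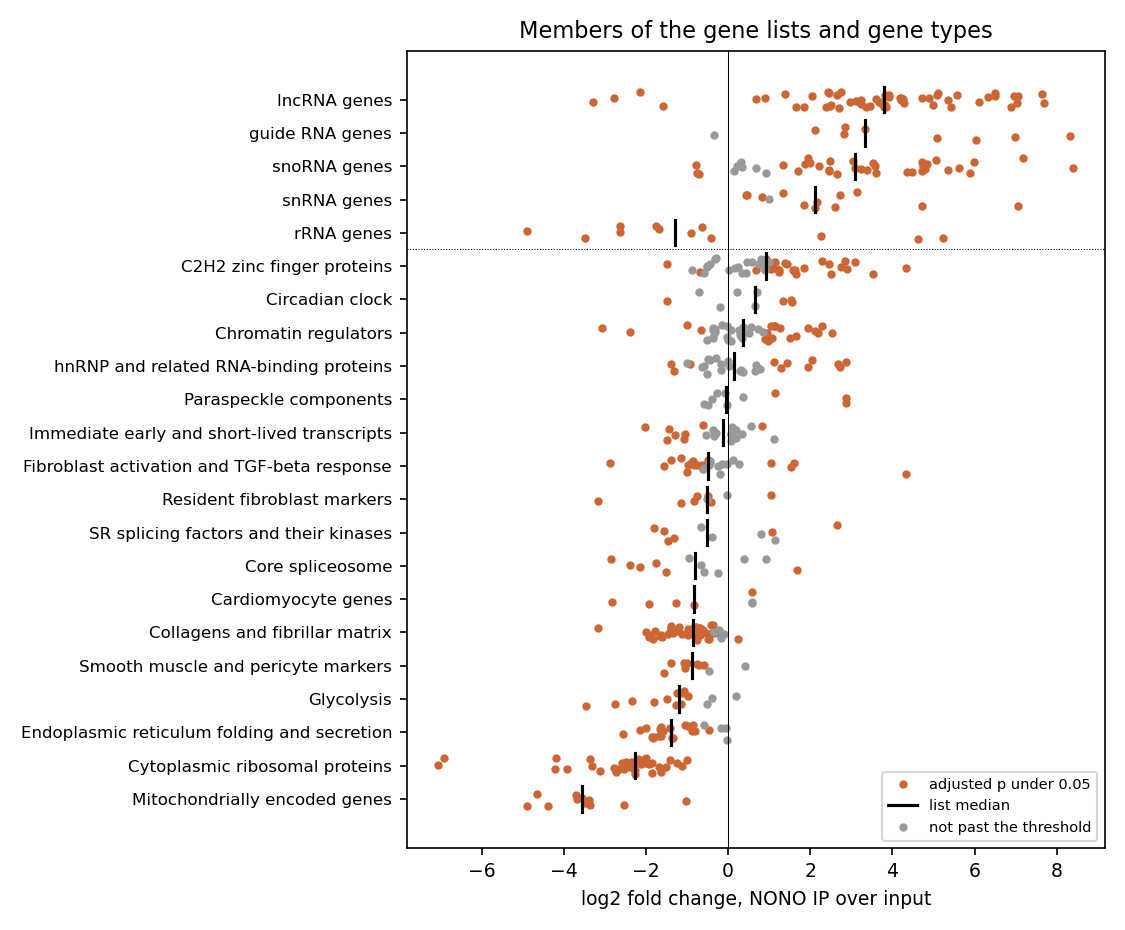
Log2 fold change of NONO IP over input (x axis) of each tested member of 17 gene lists and, above the dotted line, of 5 gene types (y axis); orange points have an adjusted p under 0.05, grey points do not, and black bars mark medians. The mitochondrial and ribosomal protein medians lie at −3.57 and −2.26 and the lncRNA median at 3.81; the chromatin regulator median of 0.36 turned below 0 with the length offset.

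RNA-binding protein genes went both ways, and camera called none of the 4 lists that hold them, while fry, which does not compare a list with other genes, called core spliceosome (adjusted p = 0.00531) and SR genes (0.0153) down. Of 10 paraspeckle component genes, 3 rose and none fell: Rbm14 (2.87, SE 0.39), Hnrnph3 (2.88, SE 0.59) and Dazap1 (1.15, SE 0.40). The median of the list was −0.06 and its mean 0.54 (camera adjusted p = 0.656, direction up). The median turned to 0.10 with the length offset, while relative to all genes it was −0.08 with TMM scaling and with library totals. Without 1 library, over 13 or 14 members, it lay between −0.07 and 0.30. The direction of the test turned down on the RPKM scales, as it did for the hnRNP list. Dazap1 and Hnrnph3 lost their calls with DESeq2 and on the RPKM scales, and Dazap1 without Input replicate 2 (adjusted p = 0.179) and without NONO IP replicate 1 (0.158). Of 28 hnRNP and related genes, 8 rose, including Hnrnpf (2.69, SE 0.22), Rbfox2 (2.04, SE 0.19) and Fubp3 (1.94, SE 0.34), and 3 fell, namely Hnrnpab, Ptbp1 and Hnrnpl, named after their values were seen (adjusted p = 0.436). Of 12 core spliceosome genes, 5 fell, namely Sf3b1 (−2.38, SE 0.37), Rbm39 (−2.86, SE 0.51), Prpf8 (−1.52, SE 0.33), Snrnp200 (−2.14, SE 0.47) and Prpf19 (−1.75), while Snrnp70 of the U1 particle rose (1.68, SE 0.15); Prpf19 and Snrnp70 were named after their values were seen. The camera adjusted p was 0.283 for this list, and 0.0330 and 0.0297 on the RPKM scales and 0.00180 with no count filter. Of 10 SR protein and kinase genes, 4 fell, namely Son (−1.57, SE 0.18), Srrm2 (−1.32, SE 0.17), Srsf2 (−1.81, SE 0.28) and Rsrp1 (−1.46, SE 0.51), while Tra2a (2.65, SE 0.46) and Luc7l2 (1.07, SE 0.26) rose, both named after their values were seen (adjusted p = 0.436). Rsrp1 lost its call under several alternatives, among them without Input replicate 2 (adjusted p = 0.289) and without NONO IP replicate 1 (0.300), and Snrnp200 without Input replicate 2 (0.101).

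Of 22 immediate early and short-lived transcripts, 7 fell, including Junb (−1.05, SE 0.19), Id3 (−1.29, SE 0.31), Ppp1r15a (−1.45, SE 0.37) and Bhlhe40 (−1.49, SE 0.40). Csrnp1, named after its value was seen, rose by 0.83. The list was not called (camera adjusted p = 0.407). Its median of −0.12 turned to 0.27 with the length offset and, relative to all genes, was −0.14 with TMM scaling and with library totals. Without 1 library, over 25 to 27 members, the median lay between −0.45 and −0.12. Junb and Id3 lost their calls with the length offset, Ppp1r15a and Bhlhe40 with DESeq2, and Bhlhe40 without Input replicate 1 (adjusted p = 0.0511). Of 9 circadian clock genes, 3 rose, among them Clock (1.56, SE 0.47) and Arntl (1.34, SE 0.50), and Bhlhe40 fell (adjusted p = 0.656, and 0.0473 with no count filter). The calls of Clock and Arntl ended on the RPKM scales and with DESeq2. Clock also lost its call without Input replicate 2 (adjusted p = 0.107) and without NONO IP replicate 1 (0.0864), and Arntl without any 1 of the 4 libraries (0.150 to 0.297). Of 7 cardiomyocyte genes, Myh7 (−2.82, SE 0.55), Gja1 (−1.93, SE 0.44), Myh6 (−1.26, SE 0.45) and Cacna1c (−0.83, SE 0.34) fell and Atp2a2, chosen after its value was seen, rose by 0.59 (SE 0.15). The list was not called (adjusted p = 0.656, and 0.0423 with no count filter). The calls of Myh6 and Cacna1c ended with DESeq2 and with library totals; that of Myh6 also ended without any 1 of the 4 libraries (adjusted p from 0.120 to 0.267), that of Cacna1c without Input replicate 1 or either NONO IP library (0.121 to 0.193), and that of Gja1 without Input replicate 1 (adjusted p = 0.101).

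Fold changes also followed gene length and abundance. Across the 2920 genes, log2 fold change correlated with relative gene length with a Spearman coefficient of 0.26 (0.32 for protein-coding genes, and 0.29 given input abundance), so longer genes were higher in the NONO IP. The coefficient was 0.14 with no count filter. Against the abundance in the other input library, it was −0.57, with −0.22 under no count filter and −0.78 with at least 50 counts in 2 libraries. Selecting genes counted in either group contributes to this relation by construction. Only the mitochondrial and ribosomal protein lists were compared with coding genes of like input abundance, whose medians were −0.60 and −0.51. The matrix, fibroblast, smooth muscle, TGF-β, endoplasmic reticulum and glycolysis lists were not. How much of their fall goes with abundance was not tested. Genes are not independent replicates, so no p-value is given for either relation.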

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

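The tests of scaling between libraries, both tests of mitochondrial genes against matched genes, the test of DNA over all listed noncoding genes, the match of lncRNAs on input abundance, the removal of the length trend from noncoding genes, and the choice of gene types were made only after the results were seen; the olfactory receptor set was corrected after its first result was seen.

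The total behind the deposited RPKM values, which enters no comparison of the report on its own, was 2.38-fold larger in the NONO IP than in the inputs (2.45 and 2.22 against 1 and 0.965, relative to Input replicate 1), while gene counts were 1.11-fold as large. One candidate explanation is genomic DNA in the NONO IP. Reads on 18 olfactory receptor genes, which fibroblasts should not express, numbered 2 and 1 in the inputs and 9 and 11 in the NONO IP, or 2.80-fold more per RPKM total (exact conditional 95% interval 0.832 to 14.7), so DNA and other sources cannot be told apart with so few reads. Olr1 shares the symbol of this family but is a lipoprotein receptor, and was left out after its 37 input and 12 NONO IP reads were seen; with it the ratio had been 0.337 (0.205 to 0.549), on the other side of 1. Reads on introns, and binding of NONO to pre-mRNA as a biological source of them, were not tested.

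Noncoding RNA classes were higher in the NONO IP. The tables argue against scaling for lncRNAs. Over all listed genes, the share of lncRNAs in the counts was 5.36-fold that of the inputs, where that of protein-coding genes was 1.12-fold. The lowest median of the 4 classes together over the scalings was 1.97, in log2, where the median of all genes was −0.54. Most of these genes passed the count filter through their NONO IP reads, so this median is no separate support. Genomic DNA stays open. Of 1372 listed noncoding genes, 106 gained at least 23 reads. Evenly spread DNA at the upper bound of the olfactory receptor density would give 75.1. That density is overstated, since receptor genes without a read are not listed, so 75.1 is too high. How far too high is not known, so this count does not decide. A median density 80.0 times the upper quartile on olfactory receptor genes (12.4 to 149.7) came from genes that mostly passed the count filter through their NONO IP reads. Gene length as the whole cause stays open. With the length trend removed, lncRNAs lay 2.93 above all genes (2.40 to 3.75) and small RNA genes 2.04 (1.44 to 3.36). LncRNAs lay 3.36 above coding genes of like length (2.81 to 4.13). Most of these noncoding genes passed the count filter through their NONO IP reads, which raises these margins, so they do not decide. Only 4 coding genes were of like length to the small RNA genes, too few for the planned match. The trend at those lengths thus has few other genes to rest on. Against coding genes of like length and input abundance, lncRNAs lay 1.12 higher (0.486 to 1.63, 36 genes). How much length and the count filter add together stays open. Binding to NONO, carry-over of nuclear RNA on beads and the siRNA named in the labels cannot be told apart, as 0 libraries with a control antibody were analysed.

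Mitochondrial and ribosomal protein RNAs were lower in the NONO IP. Scaling alone is argued against, since the higher of both medians never rose above −1.81 in log2. Ribosomal protein genes lay at −1.20 relative to other coding genes of like length (95% interval −1.46 to −0.756) and at −1.76 relative to those of like input abundance (−2.15 to −1.36), and for mitochondrial genes these differences were −2.73 (−3.80 to −1.89) and −2.97 (−3.79 to −2.30). Loss of short RNAs alone and loss of abundant RNAs alone are thus each argued against as the whole cause. Genes were not matched on length and abundance together, so the joint effect of both stays open. The coding genes matched in length to ribosomal protein genes were themselves at −1.06. A lower share of RNA from cytoplasm and mitochondria in a nuclear precipitate stays open as a hypothesis, as does the knockdown the labels name, neither of which was tested.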

How the results depend on the processing

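Leaving out ribosomal RNA genes and testing gene types were chosen after seeing the data. Over 16 alternatives, 1168 single-gene values of the 80 named genes kept direction and side of the threshold, 79 kept direction but not the call, and 2 reversed; for gene lists under 15 of these the numbers were 219, 14 and 8, and 5 gained a call. Both single-gene reversals were of Tagln, at 0.44 with the length offset and 0.45 with the length offset and block. The direction of the list test reversed for chromatin regulators (medians −0.0485 and −0.0506) and immediate early genes (0.27 and 0.27) under those fits, and on the RPKM scales for hnRNP genes (−0.69 and −0.83) and paraspeckle components (−0.66 and −0.71). Library totals gave 444 genes lower in IP, 293 of them 2-fold, and 1219 genes higher in IP. The DESeq2 Wald test gave 453 higher and 423 lower genes, with 435 genes at least 2-fold higher in IP and 357 genes at least 2-fold lower in IP; 876 of its calls were shared with the main test, all in the same direction. Requiring at least 50 counts in 2 libraries left 600 genes, with 254 higher and 247 lower, 177 and 136 of them 2-fold, and 1 list up and 4 down. Log2(RPKM + 1) gave 393 higher and 1425 lower genes, 382 and 1390 of them 2-fold, with 1 list up. Log2(RPKM + 0.1) gave 348 higher, 341 and 1118 2-fold higher and lower, and 1 list up. The length offset left 1 list up, and with the block 1 up and 5 down. With an estimated correlation, on 2 residual degrees of freedom, camera kept none of its 10 list calls (0 up and 0 down). Camera gave 2 up and 8 down with the preset correlation, and fry gave 2 up and 10 down. Nono was at −2.68 with DESeq2 size factors. The length relation was 0.14 with no count filter, and the abundance relation −0.22 with no count filter and −0.78 with at least 50 counts. Apart from fewer genes or libraries, the cause was not tested. Leaving out 1 library at a time gave between 679 and 810 higher and 615 and 705 lower genes, between 1 and 2 lists up and 8 down in each case, and a Nono log2 fold change between −3.20 and −2.01; a group's lone library is then assumed to vary like the other group. The replicate number as a block gave 870 higher and 806 lower genes. Deviations of same-numbered libraries correlated at 0.05 over genes, with 2 pairs, so the numbers were not taken to pair the libraries. List tests on DESeq2 output and Nono under limma-voom, the stricter filter or the length offset were not run. The simulation, run only at the real depth and with 2 libraries per group, recovered 63.3% of 2-fold changes.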

Other observations

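The test of host genes was planned before its result was seen; the genes of the next paragraph were chosen after their values were seen.

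Ribosomal RNA species did not move together. The 18S gene LOC120099695 changed by −2.63 (SE 0.09) and Rn28s by −0.91 (SE 0.05), whereas 3 copies of 5S rRNA rose: LOC120100110 had 0 and 1 input reads and 34 and 33 NONO IP reads, LOC120102552 had 0 and 1 against 19 and 25, and LOC120098340 had 0 and 5 against 17 and 20. Copies of 5S rRNA share reads. On the scaffold of the ribosomal DNA, Rn45s, the 45S precursor, changed by −0.64 (SE 0.05), while the neighbouring predicted gene LOC310926 rose from 112 and 112 reads to 1285 and 992 (2.75, SE 0.12, adjusted p = 1.7e-12). Rn7sl1, the RNA of the signal recognition particle, fell from 1548 ± 3.81 to 323 ± 17.3 CPM.

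Several lists had too few tested members for a list test. Of the genes of 3′ end processing, Papola, poly(A) polymerase, rose by 3.09 (SE 0.41) and Pabpn1 by 1.67 (SE 0.22), Sympk changed by −1.18 (SE 0.39), and Pcf11 did not pass. The histone genes Hist2h4, H1f2 and H1f4 were lower, Hist2h4 with a ratio of 12.5 (exact interval 3.82 to 64.8) and H1f2 and H1f4 at −1.30 (SE 0.33) and −1.76 (SE 0.47). Of nuclear-encoded oxidative phosphorylation, Atp5f1a changed by −2.23 (SE 0.45) and Sdha by −1.69 (SE 0.49), and Atp5f1b did not pass. Of endothelial markers, Eng changed by −0.85 (SE 0.19) and Flt1 did not pass. Of the list of nuclear lncRNAs, Pvt1 rose and Rpph1, which is not of the lncRNA type in the deposited tables, did not pass. Ccnd1 of the cell cycle list and Isg20 of the interferon list did not pass. No member of the skeletal myoblast, macrophage, epicardial or double-strand break repair lists was tested; epicardial markers summed to 23 and 24 input reads and 30 and 27 NONO IP reads, and repair genes to 42 and 38 against 29 and 35.

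Since snoRNA and guide RNA genes often lie in introns, a hypothesis was that protein-coding genes hosting a small RNA gene may be higher in the NONO IP. It was tested for genes whose span holds a snoRNA, snRNA or miRNA gene on either strand, and was not borne out for them. Guide RNA genes, although planned, were not included, so their hosts were not tested as hosts. The 196 host genes among 2687 coding genes found in the RefSeq table had a median log2 fold change of −0.21, which was 0.14 below the median of 10000 lists of other coding genes matched on input abundance (difference −0.143), inside the 95% range of those lists (−0.25 to 0.12). Of the host genes 52 were higher and 72 lower. Khdc4 and Spaca6 were the 2 of the 12 genes with the largest increase that hold a small RNA gene of these types.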
